A study of Synechocystis sp. PCC 6803 with 8 samples.

How the data were processed

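The samples were total RNA of 8 cultures, from the WT and the sml0013 mutant at HC and 24 h after the shift to LC, 2 biological replicates per group, each on 1 Agilent array. Per the labels, cells grew at 130 µmol photons per square metre and second and 29 °C, the mutant with 50 µg/ml kanamycin, and RNA was labelled with Cy3 directly, without cDNA synthesis, in aliquots of 2 µg. Direct labelling keeps the strand of the RNA, and the array design names coding, antisense, noncoding, internal and 5' UTR features.

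The deposited scanner tables hold intensity values of each spot, read by the authors with Agilent Feature Extraction 10.7.3.1, per the file headers. The column used here is the processed signal, an intensity after subtraction of a fitted spatial background and after detrending within the array, per the file headers, with no scaling between arrays. The flags for spots well above background, saturated spots and outlier spots come from the same software. The deposited value table of the authors appears to be on a log2 scale: each column ranked the spots exactly as the raw median intensity of that array (Spearman 1.00), the sorted values of the columns were nearly alike and the column medians were all 11.08, as quantile normalization without background subtraction would give. Its scale and normalization are inferred from the values and not given in the sources used here. The submitters' processing notes name limma, with no version, design or threshold.

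Each array held 42303 spots, 40886 of them not controls, for 20363 probes and 8830 gene features. Control spots and spots with an outlier flag (2 to 8 per array) were left out. The log2 of the processed signal minus the 75th percentile of its array was averaged over the spots of a probe, and then over the probes of a gene feature. A feature was tested where at least 1 probe was well above background on both arrays of at least 1 group, which left 8145 features, of which 3329 were coding, 1494 antisense and 541 noncoding. Spots well above background made up 85.8% to 92.0% of each array and 0 were saturated. Negative control spots had a mean net signal of 42.1% to 50.0% of the median spot signal on the LC arrays and 30.4% to 40.3% on the HC arrays. The share of background therefore differed between the CO2 levels. The number of arrays, 2 per group, limits the precision. Replicate arrays correlated with r from 0.994 to 0.997 across features, and the median SD between replicates was 0.05 to 0.08 on the log2 scale.

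All 8 arrays entered 1 fit with a mean per group (lmFit and eBayes in limma 3.58.1, R 4.3.3), because 4 groups of 2 share 1 estimate of the spread. The 5 comparisons were LC against HC in each strain, the mutant against the WT at each CO2 level, and their interaction. p-values were adjusted by the Benjamini-Hochberg method over all features tested, and a feature was called at an adjusted p under 0.05. Calls of at least 2-fold are given beside the total. In the same fit, 27 lists of genes were tested against all other coding genes with camera, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over all 120 tests of lists with tested members. Of these tests, 53 passed with the preset correlation and 0 with the estimated one, where the smallest adjusted p was 0.485. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered carbon uptake, the mnh operon, flavodiiron proteins, carbon regulators, carboxysome and Rubisco, the NDH-1 core, both photosystems, phycobilisome, ATP synthase, electron carriers, nitrogen assimilation, photorespiration, sugar catabolism, Calvin cycle, chaperones, high light stress, ribosomal proteins, tetrapyrrole synthesis, type IV pili, phosphate uptake, the hydrogenase and the plasmids pSYSA, pSYSM, pSYSX and pSYSG. The lists for pSYSM, pSYSX and pSYSG had 0 tested members.

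A gene with no probe reading above background in a group has only a bound there. The fold was then taken from the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the gene's own value and the lowest signal among probes well above background on that array, and given as at least that fold. Where some readings (probe by array) were above background, their number is given. The rule named sml0013, for each comparison the coding genes with the largest changes in each direction among called genes whose groups do not overlap, up to 3 noncoding or antisense features in each direction, the members of 4 carbon and electron transfer lists, and up to 4 members of the other lists. Of the named values that passed the test, 174 came from this rule, and in all 174 the arrays of the groups did not overlap. The rule itself asked for this in the genes and features with the largest changes. Members of lists named without passing the test are not in this count. Values of gifA and gifB in the WT response and most values of slr0797, slr0798, sll0792 and sll0794 were chosen after their values were seen.

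Gene symbols come from the lists fixed beforehand and other genes are given by the identifier on the array. The reference table in reach (assembly ASM28445v1) matched 0 of the 3364 coding identifiers, so genome coordinates are not given and the genes beside sml0013 were not named. Probes of a gene were averaged even where they disagreed: of 3224 coding genes with several probes, 255 (WT LC against HC), 553 (mutant LC against HC), 5 (mutant against WT at HC), 219 (mutant against WT at LC) and 59 (interaction) had probes called in both directions. Slides and scan days were read from the files: both HC groups shared slide 2, the WT LC arrays were on slide 1 and the mutant LC arrays on slide 3, and slide 1 was scanned on a day of its own. Mutant against WT at HC was therefore also fitted within its slide. For the other comparisons no fit with slide as a term could be had.

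Alternatives were normexp background correction with an offset of 50 (with the 75th percentile, and with quantile normalization), quantile normalization alone, scaling to the median, the authors' processed values, no filter, a filter on all 8 arrays, the median of probes, single probes, a variance prior with trend and robust, only the groups compared, array weights, the replicate number as a block, each array left out in turn, and, chosen after seeing the data, the fit without the dim HC arrays, the crossed pairing and cyclic loess. No scaling moved the median change of all features by more than 0.1 on the log2 scale. Each scaling brings the arrays to a common level, as the authors' values also appear to be. This therefore cannot show whether all features shifted together between the groups.

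The steps were tested on simulated data, with 50 features changed per size and comparison among 8145 features. For the WT response, 8% of features changed by 0.25 on the log2 scale were recovered, 50% of those changed by 0.5, 78% at 1 and 96% at 2, and for the mutant response 4%, 32%, 88% and 96%. For the mutant against the WT the shares were 10%, 66%, 90% and 94% at HC and 8%, 36%, 88% and 92% at LC, and for the interaction 0%, 36%, 72% and 90%. Of unchanged features, 6 to 10 were called per comparison. In the data 26.4% to 78.7% of features were called, far more than were changed here, so these shares need not carry over. Gene lists were simulated only for the mutant against the WT at HC, each moved by 1 on the log2 scale with other genes unchanged. Of these, 19 of 19 moved ones were called among 3329 coding genes, also with an estimated correlation, and 0 of 342 others. The lists called there in the data had medians of 0.35, 0.18 and -0.56, so changes of that size were not tried. The simulation drew each gene independently and left out differences between slides. It therefore did not try the list tests on correlated genes. In the data the estimated correlation of these lists ran from -0.08 (carboxysome and Rubisco) to 0.61 (ribosomal proteins). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures, and statmod 1.5.0 was loaded with limma.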

Results

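RNA was measured in the unicellular cyanobacterium Synechocystis sp. PCC6803, in the wild type (WT) and in a mutant in which the gene sml0013 was disrupted with a kanamycin resistance cassette. The series describes sml0013 as encoding a subunit of NDH-1, the thylakoid complex that passes electrons into the plastoquinone pool and also drives CO2 uptake. Cultures grew at high CO2 (HC, 5%) or were taken 24 h after a shift to ambient air with 0.035% CO2 (low CO2, LC). The 4 groups held 2 biological replicates each (n = 2 arrays per group), and each replicate was hybridised to its own one-colour array, 8 arrays in all. Between 85.8% and 88.6% of the spots of an LC array and between 89.1% and 92.0% of those of an HC array were well above background, and 0 spots were saturated. The number of arrays limits the precision of every value. Replicate 2 of both HC groups was dimmer than the other arrays, with a 75th percentile of 896 (WT) and 873 (mutant) intensity units against 1606 to 6113 on the others. Levels are given as log2 signal relative to the 75th percentile of the array, and changes as log2 differences ± SE from limma. Both HC groups were on 1 slide, while the WT LC and mutant LC arrays each filled a slide of their own. For every comparison except mutant against WT at HC, slide and group therefore cannot be told apart. The mutant cultures had kanamycin in the medium and none is named for the WT, so every comparison of the strains, the interaction included, is also one of cultures with and without the antibiotic.

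The targeted gene was examined first, as a check of the strain labels. In the WT, sml0013 had a level of 0.27 ± 0.01 (SD, n = 2 arrays) at HC and 0.67 ± 0.05 at LC. In the mutant its only probe was not well above background on any array, which put sml0013 at least 29.7-fold lower than in the WT at HC and at least 27.0-fold lower at LC (limma, adjusted p = 4.84e-07 and 5.28e-07). The noncoding feature NC-870 followed the same pattern, at least 29.3-fold lower at HC and at least 26.7-fold lower at LC. Where the probe lies relative to the cassette is not given in the sources used here. In the WT, sml0013 rose by 0.40 ± 0.09 from HC to LC (limma, adjusted p = 0.00511). This call ended with normexp background correction and the 75th percentile (log2 change 0.35, adjusted p = 0.263 in limma), but held with normexp and quantile normalization.

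**Figure D1:**
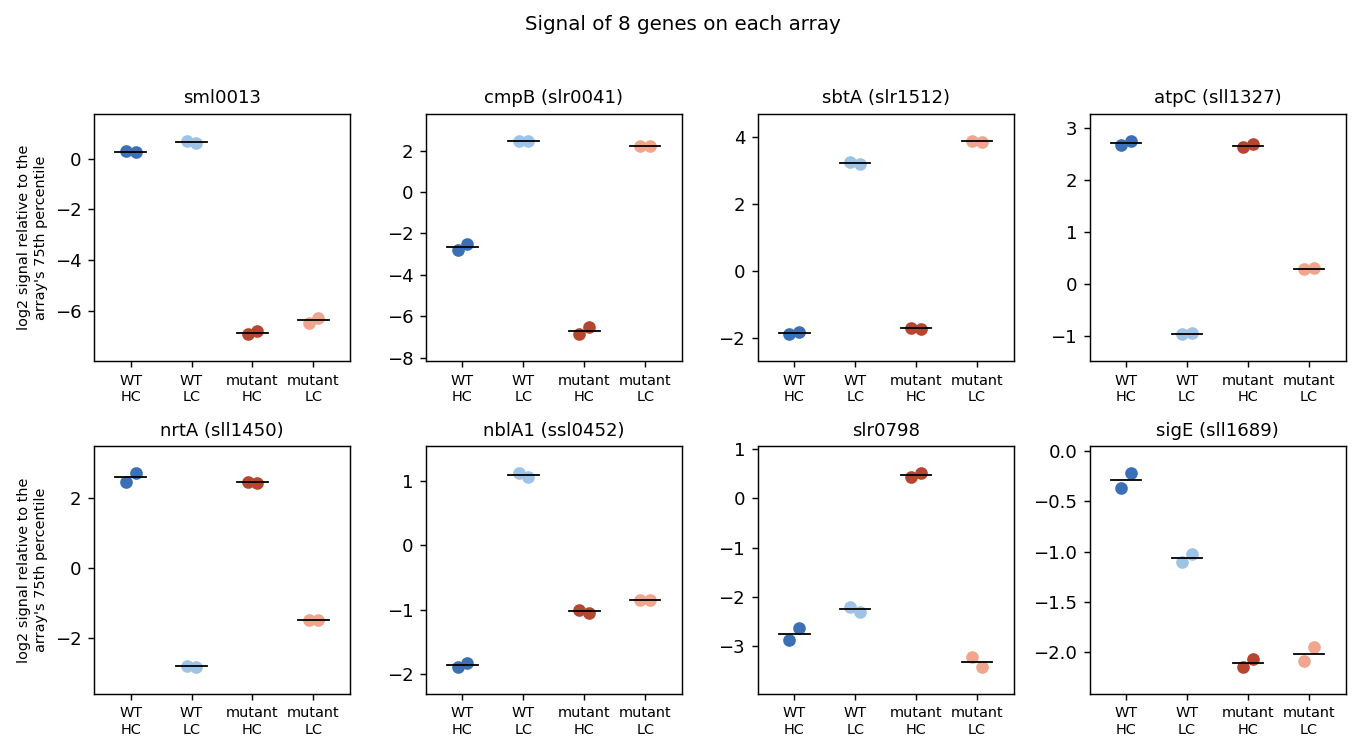
Signal of 8 genes on each of the 8 arrays (vertical axes: log2 signal relative to the 75th percentile of the array; horizontal axes: the 4 groups; points: single arrays; black lines: means of 2 arrays). sml0013 in the mutant and cmpB in the mutant at HC were not well above background, and cmpB differed between the strains at HC while sbtA did not pass the test there.

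The comparison of LC with HC in the WT asks which transcripts respond to carbon limitation. All 10 tested genes of inducible inorganic carbon uptake rose, with a median log2 change of 4.73 (camera in limma, adjusted p = 8.65e-07, and 0.485 with an estimated correlation). Among them were ndhF3 (sll1732, 64.0-fold, with 7 of 8 probe readings above background at HC) and ndhD3 (sll1733, 5.45 ± 0.07) of the inducible CO2 uptake complex, the bicarbonate transporter subunit cmpB (slr0041, 5.12 ± 0.13) and the sodium-dependent bicarbonate transporter sbtA (slr1512, 5.06 ± 0.06). Of the flavodiiron genes, which serve in photoprotective electron transfer, flv4 (sll0217) was not above background at HC and rose at least 299-fold. The neighbouring genes sll0218 (8.87 ± 0.13) and flv2 (sll0219, 7.86 ± 0.10) rose as well, with 3 and 6 of 8 probe readings above background at HC. flv3 (sll0550, 1.55 ± 0.06) also rose, whereas flv1 (sll1521) fell by 0.52. The list of these 5 genes (flv1 to flv4 and sll0218) had a median of 7.86 (camera, adjusted p = 0.0136, and 0.485 with an estimated correlation).

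In the same comparison, 16 of the 17 core NDH-1 genes rose, led by ndhA (sll0519, 1.76 ± 0.06) and ndhI (sll0520, 1.69 ± 0.06), and ndhF1 (slr0844) fell by 0.65 (median 1.30; camera, adjusted p = 1.02e-05, and 0.485 with an estimated correlation). In the mnh operon, which encodes subunits of a sodium/proton antiporter, 7 of 8 genes rose, among them slr2006 (2.52 ± 0.11) and slr2007 (2.12 ± 0.06), and slr2013 stood at -0.08 ± 0.08 (median 0.87; camera, adjusted p = 0.00329, and 0.485 with an estimated correlation). The carbon uptake regulators ndhR (sll1594, 3.30 ± 0.11) and cmpR (sll0030, 1.75 ± 0.12) rose, while the list of 5 regulators as a whole did not pass the test (2 higher, 1 lower; camera, adjusted p = 0.240). The constitutive uptake genes went the other way: all 4 fell, including cupB (slr1302, -1.80 ± 0.07) and the transporter bicA (sll0834, -1.65 ± 0.08), with a median of -1.36 (camera, adjusted p = 0.0359, and 0.485 with an estimated correlation). Of 12 carboxysome and Rubisco genes 10 fell and 1 rose (median -0.97; camera, adjusted p = 0.0183, and 0.485 with an estimated correlation), with ccmM (sll1031) at -1.65 ± 0.09 and ccmN (sll1032) at -1.61 ± 0.08.

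All 23 ribosomal protein genes fell in the WT at LC (median -2.56; camera, adjusted p = 5.86e-08, and 0.485 with an estimated correlation), for example rplE (sll1808, -3.00 ± 0.07) and rpsQ (ssl3437, -2.91 ± 0.07). All 9 ATP synthase genes fell (median -3.05; camera, adjusted p = 0.000186, and 0.485 with an estimated correlation), with atpC (sll1327) at -3.68 ± 0.06 and atpA (sll1326) at -3.20 ± 0.07. In nitrogen assimilation 12 of 17 genes fell and 3 rose (median -3.76; camera, adjusted p = 0.0103, and 0.485 with an estimated correlation). The nitrate transporter genes nrtA (sll1450, -5.40 ± 0.09) and nrtB (sll1451, -5.01 ± 0.07), the glutamine synthetase gene glnA (slr1756, -4.52 ± 0.07) and the ammonium transporter gene amt1 (sll0108, -4.50 ± 0.09) were among those that fell. The genes of the inactivating factors of glutamine synthetase, gifA (ssl1911, 3.21 ± 0.11) and gifB (sll1515, 3.07 ± 0.08), rose. All 10 Calvin cycle genes fell (median -1.55; camera, adjusted p = 0.00322, and 0.552 with an estimated correlation), including rpiA (slr0194, -2.96 ± 0.09), tpi (slr0783, -2.62 ± 0.07) and tktA (sll1070, -2.46 ± 0.06).

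All 15 phycobilisome genes, which encode the light-harvesting antenna, fell in the WT (median -1.09; camera, adjusted p = 0.000625, and 0.552 with an estimated correlation), with apcA (slr2067) at -2.04 ± 0.11 and apcB (slr1986) at -1.96 ± 0.08. The phycobilisome degradation genes nblA1 (ssl0452, 2.96 ± 0.06) and nblA2 (ssl0453, 2.30 ± 0.07) rose. All 12 genes of tetrapyrrole synthesis fell (median -0.94; camera, adjusted p = 0.00362, and 0.485 with an estimated correlation), among them por (slr0506, -2.18 ± 0.07). The chaperonin genes groES (slr2075, -4.53 ± 0.14), groEL2 (sll0416, -4.49 ± 0.07) and groEL1 (slr2076, -4.45 ± 0.14) fell, in a list of 15 chaperones and proteases with 4 genes higher and 10 lower (camera, adjusted p = 0.202). Of 12 type IV pilus genes 9 rose and 3 fell (median 0.89; camera, adjusted p = 0.0307, and 0.586 with an estimated correlation), with the pilin genes pilA2 (sll1695) at 2.63 ± 0.07 and pilA1 (sll1694) at 2.56 ± 0.09. On plasmid pSYSA 46 of 95 tested genes rose and 9 fell (median 0.34; camera, adjusted p = 0.000607, and 0.688 with an estimated correlation).

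Of the lists that did not pass camera in the WT comparison, all but the hydrogenase held members that moved both ways. Photosystem II had 6 of 24 genes higher and 15 lower (adjusted p = 0.159 in camera), including psbO (sll0427, -2.28 ± 0.08). Electron carriers and oxidases had 3 of 16 higher and 11 lower (camera, adjusted p = 0.0940), with ferredoxin petF (ssl0020) at -2.51 ± 0.13. Photorespiration had 2 of 9 higher and 5 lower (camera, adjusted p = 0.594), with the glycerate kinase gene glyk (slr1840) at -2.98 ± 0.11. Photosystem I had 4 of 12 higher and 5 lower (camera, adjusted p = 0.853), and sugar catabolism and glycogen 5 of 18 higher and 11 lower (camera, adjusted p = 0.383). The list of high light and oxidative stress had 4 of 15 higher and 7 lower (camera, adjusted p = 0.896), phosphate uptake 7 of 12 higher and 5 lower (camera, adjusted p = 0.511), and the bidirectional hydrogenase 3 of 5 higher and 0 lower (camera, adjusted p = 0.135). Adjusted over the list alone, the counts of all lists in the WT comparison were the same as over all genes, except for pSYSA with 45 higher and 8 lower.

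Over all features, limma called 6388 of 8145 changed in the WT (3596 higher, 2792 lower), of which 2301 changed at least 2-fold (1132 higher, 1169 lower). Of the 3329 coding genes tested, 1135 were higher and 1498 lower. The arrays of both groups did not overlap for 7301 features, where chance gives 33.3%. With the authors' processed values, 19 of 60 named log2 changes and the medians of 6 of 14 called lists were over 1.5 times smaller, with the sign kept (nitrogen assimilation -1.79, and -2.49 with normexp).

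The same comparison in the mutant asks how the strain without sml0013 responds to the shift. All 10 inducible carbon uptake genes rose there too (median 5.97; camera, adjusted p = 3.36e-07, and 0.485 with an estimated correlation). cmpB (slr0041) was not above background in the mutant at HC and rose at least 113-fold. The other bicarbonate transporter genes cmpC (slr0043, 7.32 ± 0.20, 1 of 8 readings above background at HC), cmpA (slr0040, 6.27 ± 0.10, 6 of 8) and cmpD (slr0044, 6.26 ± 0.13, 4 of 8) rose, as did slr0042 (7.60 ± 0.06, 2 of 8). flv4 (sll0217) rose at least 323-fold, flv2 (sll0219) by 8.16 ± 0.10 with 3 of 8 readings at HC, ndhF3 (sll1732) by 6.07 ± 0.11, ndhD3 (sll1733) by 5.86 ± 0.07 and sbtA (slr1512) by 5.58 ± 0.06.

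In the mutant 16 of 17 core NDH-1 genes rose and 1 fell (median 1.23; camera, adjusted p = 9.18e-06, and 0.485 with an estimated correlation), with ndhA (sll0519) at 1.90 ± 0.06. All 8 mnh genes rose (median 1.09; camera, adjusted p = 0.000433, and 0.485 with an estimated correlation), with slr2006 at 3.04 ± 0.11. All 23 ribosomal protein genes fell (median -2.62; camera, adjusted p = 3.91e-08, and 0.485 with an estimated correlation), with rplE (sll1808) at -2.94 ± 0.07. All 9 ATP synthase genes fell (median -2.11; camera, adjusted p = 0.000449, and 0.485 with an estimated correlation), with atpC (sll1327) at -2.37 ± 0.06. In nitrogen assimilation 13 of 17 genes fell and 3 rose (median -2.62; camera, adjusted p = 0.0103, and 0.485 with an estimated correlation), with nrtA (sll1450) at -3.93 ± 0.09 and gifA (ssl1911) at 4.32 ± 0.11. Of the Calvin cycle genes 9 of 10 fell (median -1.13; camera, adjusted p = 0.0114, and 0.586 with an estimated correlation). Photosystem I had 9 of 12 genes higher and 1 lower (median 0.45; camera, adjusted p = 0.0254, and 0.553 with an estimated correlation), with psaM (smr0005) at 1.04 ± 0.09 and psaE (ssr2831) at 0.75 ± 0.06. All 5 hydrogenase genes rose (median 0.71; camera, adjusted p = 0.0179, and 0.586 with an estimated correlation), with hoxE (sll1220) at 1.01 ± 0.06. Of the phycobilisome genes 3 of 15 rose and 9 fell (median -0.43; camera, adjusted p = 0.371). Among single genes, pgr5 (ssr2016), which acts in cyclic electron flow around photosystem I, stood at -3.61 ± 0.10, groEL2 (sll0416) at -3.82 ± 0.07 and slr0798, known as a zinc exporter, at -3.79 ± 0.11 with 5 of 8 readings above background at LC. Adjusted over the list alone, these counts were the same as over all genes.

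limma called 6411 of 8145 features changed in the mutant (3721 higher, 2690 lower), of which 2411 changed at least 2-fold (1306 higher, 1105 lower). Of the coding genes, 1155 were higher and 1475 lower. The groups' arrays did not overlap for 7319 features, where chance gives 33.3%. Across the 3329 coding genes, which are not independent replicates, the responses of both strains correlated with r = 0.911 and a slope of 0.886 for the mutant on the WT. They shared no array, but both HC groups were on the same slide, which held no LC array. A shift of that slide would enter both responses alike and could raise the correlation and the shared counts below. Of the coding genes higher at LC, 925 were shared between the strains where independent lists would share 394, and 1273 lower genes were shared where 664 would be. Another 75 coding genes were called in opposite directions. With the authors' processed values, 16 of 33 named log2 changes in the mutant and the medians of 7 of 14 called lists were over 1.5 times smaller, with the sign kept (nitrogen assimilation -1.14).

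**Figure D2:**
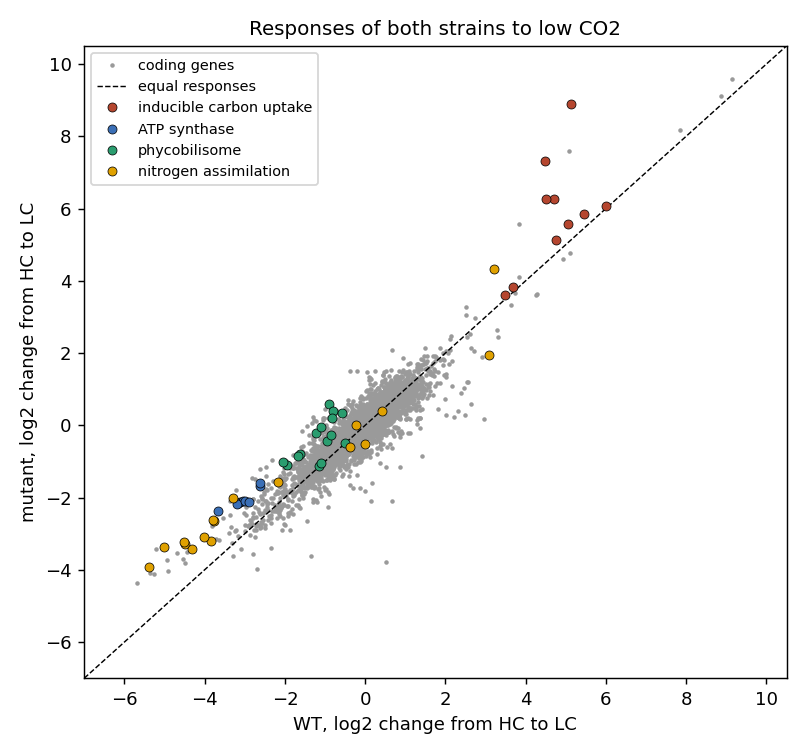
Log2 change from HC to LC in the mutant (vertical axis) against that in the WT (horizontal axis) for 3329 coding genes (points), with 4 gene lists in colour and a dashed line of equal responses. The values are fitted ones, also for genes not above background in a group. Genes of ATP synthase, phycobilisome and nitrogen assimilation that fell in the WT lie mostly above the line, and across all coding genes r was 0.911.

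The comparison of the mutant with the WT at HC asks how the mutant, grown with kanamycin, differs when CO2 is plentiful. The bicarbonate transporter genes were lower in the mutant: cmpB (slr0041) was not above background there and at least 3.89-fold lower (limma, adjusted p = 2.87e-05), cmpC (slr0043) stood at -2.88 ± 0.20, cmpD (slr0044) at -1.90 ± 0.13 and cmpA (slr0040) at -1.86 ± 0.10. slr0042 was lower by the same test (-2.80 ± 0.06). Of 8 probe readings in the mutant, 1 was above background for cmpC, 4 for cmpD, 6 for cmpA and 2 for slr0042. The other inducible carbon uptake genes did not follow: sbtB (slr1513) was higher (0.56 ± 0.06), and ndhD3 (sll1733, -0.22 ± 0.07), sbtA (slr1512, 0.14 ± 0.06) and ndhF3 (sll1732, 0.02 ± 0.11) did not pass the test. The list of 10 had 1 gene higher and 4 lower (1 and 5 adjusted over the list alone; camera, adjusted p = 0.174).

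The largest positive differences at HC were in slr0798 (3.23 ± 0.11), pgr5 (ssr2016, 2.02 ± 0.10) and slr0797 (1.61 ± 0.07), the latter known as a cobalt exporter. The high light inducible gene hliB (ssr2595, 1.25 ± 0.09), nblA1 (ssl0452, 0.84 ± 0.06) and nblA2 (ssl0453, 0.73 ± 0.07) were higher too. Lower in the mutant were the group 2 sigma factor gene sigE (sll1689, -1.82 ± 0.08), which acts on sugar catabolism, and the glycolytic genes gap1 (slr0884, -1.15 ± 0.08) and pfkA1 (sll1196, -0.74 ± 0.10), in a list of 18 sugar catabolism genes with 1 higher and 8 lower (camera, adjusted p = 0.0763). The genes of the light-independent protochlorophyllide reductase, chlL (slr0749, -1.64 ± 0.08) and chlB (slr0772, -1.49 ± 0.10), were lower, and so was gifA (ssl1911, -1.70 ± 0.11). Also lower were the cytochrome oxidase genes ctaE (slr1138, -1.10 ± 0.07), ctaC (slr1136, -1.09 ± 0.07) and ctaD (slr1137, -1.08 ± 0.06), and the phycobilisome linker gene cpcG2 (sll1471, -1.09 ± 0.07). sll0514 (-3.05 ± 0.10) and slr1634 (-2.16 ± 0.07), outside the lists, were lower as well.

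As groups, the ribosomal protein genes were higher in the mutant at HC, 18 of 23 (21 adjusted over the list alone) with 0 lower and a median of 0.35 (camera, adjusted p = 3.91e-08, and 0.485 with an estimated correlation), for example rplC (sll1799, 0.54 ± 0.07). All 5 hydrogenase genes were lower, also adjusted over the list alone, with a median of -0.56 (camera, adjusted p = 0.00613, and 0.552 with an estimated correlation), led by hoxE (sll1220, -0.74 ± 0.06). Of the carboxysome and Rubisco genes 4 of 12 were higher, also adjusted over the list alone, including ccaA (slr1347, 0.43 ± 0.06), with a median of 0.18 (camera, adjusted p = 0.00648, and 0.485 with an estimated correlation) that was 0.11 without mutant HC replicate 2. In the core NDH-1 list 2 of 17 genes were higher and 3 lower, the same adjusted over the list alone (median -0.05; camera, adjusted p = 0.954). limma called 2380 of 8145 features different at HC (1026 higher, 1354 lower), of which 145 differed at least 2-fold (33 higher, 112 lower). Among coding genes 1220 differed (515 higher, 705 lower). The groups' arrays did not overlap for 5195 features, where chance gives 33.3%. Scaled to the median, the split was 1279 higher and 1116 lower, 53.4% higher against 43.1%. A fit of the 4 arrays of this slide alone called 1148 (448 higher, 700 lower), and 1407 were called without mutant HC replicate 1, 1554 without WT HC replicate 2, and 991 without both dim HC arrays, a fit chosen after seeing the data. normexp with the 75th percentile called 1550. With the authors' processed values 24 of 32 named log2 changes and the median of 1 of 3 called lists (hydrogenase, -0.25) were over 1.5 times smaller.

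The comparison of the mutant with the WT at LC asks how the mutant, again grown with kanamycin, differs under carbon limitation. All 9 ATP synthase genes were higher in the mutant, with a median of 1.11 (camera, adjusted p = 1.29e-07, and 0.485 with an estimated correlation), for example atpH (ssl2615, 1.28 ± 0.07), atpC (sll1327, 1.25 ± 0.06) and atpD (sll1325, 1.16 ± 0.08). In nitrogen assimilation 10 of 17 genes were higher and 5 lower (median 0.72; camera, adjusted p = 0.00673, and 0.485 with an estimated correlation), with glnA (slr1756) at 1.52 ± 0.07, nrtA (sll1450) at 1.33 ± 0.09 and nrtB (sll1451) at 1.28 ± 0.07. The urea transporter gene urtA (slr0447) stood at 1.43 ± 0.07. Of the phycobilisome genes 12 of 15 were higher and 0 lower (median 0.54; camera, adjusted p = 6.58e-06, and 0.485 with an estimated correlation), with apcA (slr2067) at 1.04 ± 0.11 and apcB (slr1986) at 1.00 ± 0.08. The phycobilisome degradation genes nblA1 (ssl0452, -1.94 ± 0.06) and nblA2 (ssl0453, -1.17 ± 0.07) were lower, as were the pilin genes pilA2 (sll1695, -1.74 ± 0.07) and pilA1 (sll1694, -1.38 ± 0.09), sigE (sll1689, -0.96 ± 0.08) and the high light inducible gene hliC (ssl1633, -1.09 ± 0.12).

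Photosystem I had 10 of 12 genes higher in the mutant at LC and 0 lower (median 0.47; camera, adjusted p = 2.88e-05, and 0.485 with an estimated correlation), with psaM (smr0005, 0.74 ± 0.09), psaK1 (ssr0390, 0.74 ± 0.08) and psaD (slr0737, 0.71 ± 0.08). Photosystem II had 15 of 24 higher and 2 lower (median 0.29; camera, adjusted p = 0.00716, and 0.688 with an estimated correlation), with psbO (sll0427) at 0.73 ± 0.08 and psbA1 (slr1181) at -0.65 ± 0.09. Of the Calvin cycle genes 8 of 10 were higher (median 0.48; camera, adjusted p = 0.000449, and 0.485 with an estimated correlation), including fbp_sbp (slr2094, 0.78 ± 0.07). Of the carboxysome and Rubisco genes 8 of 12 were higher and 1 lower (median 0.48; camera, adjusted p = 0.000449, and 0.485 with an estimated correlation), including ccmK1 (sll1029, 0.75 ± 0.06). Ribosomal protein genes were higher in 17 of 23 cases with 0 lower (median 0.37; camera, adjusted p = 2.11e-06, and 0.553 with an estimated correlation). Of the phosphate uptake genes 6 of 12 were lower and 1 higher (median -0.29; camera, adjusted p = 0.0136, and 0.485 with an estimated correlation), a list call that ended with normexp and quantile normalization (adjusted p = 0.0550 in camera), with sll0680 at -0.59 ± 0.07. Adjusted over the list alone, the counts were 13 and 0 for the phycobilisome, 15 and 3 for photosystem II, 9 and 1 for the carboxysome, 19 and 0 for ribosomal proteins and 1 and 9 for phosphate uptake (higher and lower), and the same as over all genes for ATP synthase, nitrogen assimilation, photosystem I and the Calvin cycle.

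Of the inducible carbon uptake genes at LC, 3 of 10 were higher in the mutant and 0 lower (4 and 1 adjusted over the list alone; camera, adjusted p = 0.172), among them sbtB (slr1513, 0.70 ± 0.06) and sbtA (slr1512, 0.66 ± 0.06), and cmpB (slr0041) stood at -0.26 ± 0.13 without passing the test. In the core NDH-1 list 3 of 17 were higher and 1 lower (2 and 1 adjusted over the list alone; camera, adjusted p = 0.429), and its median of 0.06 turned negative under another scaling, down to -0.07. limma called 3409 of 8145 features different at LC (1664 higher, 1745 lower), of which 196 differed at least 2-fold (92 higher, 104 lower). Among coding genes 1563 differed (712 higher, 851 lower). The share higher among the features called, 48.8%, was 51.5% scaled to the median and 53.3% with cyclic loess, the latter chosen after seeing the data. The groups' arrays did not overlap for 6276 features, where chance gives 33.3%. The count was 1853 without WT LC replicate 1, 2038 without mutant LC replicate 1, 2067 without mutant LC replicate 2 and 2105 without WT LC replicate 2. With the authors' processed values, 14 of 36 named log2 changes and the medians of 3 of 9 called lists were over 1.5 times smaller (nitrogen assimilation 0.29). Across the 3329 coding genes, which are not independent replicates, the strain differences at HC and at LC, which share no array, correlated with r = 0.315. There were 189 genes higher in the mutant in both (110 for independent lists), 314 lower in both (180) and 174 called in opposite directions.

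**Figure D3:**
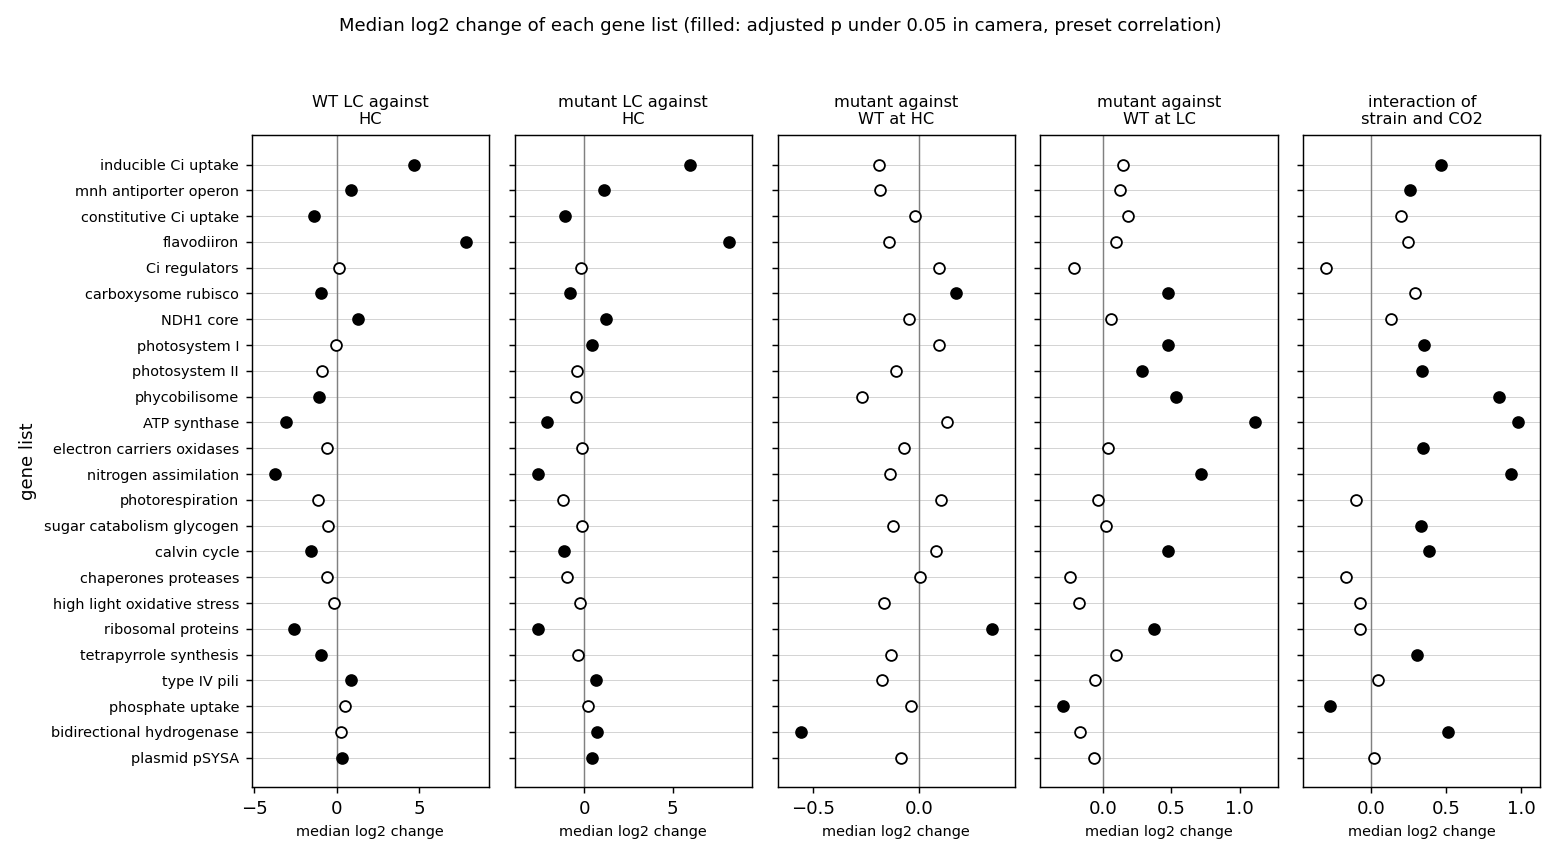
Median log2 change (horizontal axes) of each of 24 gene lists (vertical axis) in the 5 comparisons (panels, each with its own scale); filled points passed camera with the preset correlation, and open points did not. The ATP synthase list stood at -3.05 in the WT response, -2.11 in the mutant response and 1.11 in the mutant against the WT at LC.

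The interaction tests whether the response to LC differs between the strains, as the response of the mutant minus that of the WT. The cmp genes had a larger increase in the mutant, with cmpC (slr0043) fitted at 2.84 ± 0.29, cmpD (slr0044) at 1.76 ± 0.19 and cmpA (slr0040) at 1.57 ± 0.14, and slr0042 at 2.51 ± 0.08. Their differences at HC were close in size and of opposite sign (-2.88, -1.90, -1.86 and -2.80). The larger increase is therefore largely the lower level in the mutant at HC seen again, and not a separate result. In the mutant at HC only 1 of 8 readings of cmpC, 4 of cmpD, 6 of cmpA and 2 of slr0042 were above background, so these sizes rest in part on background readings. cmpB (slr0041) was not above background in the mutant at HC, where the fit gave 3.78 ± 0.19 and the bound on the mutant response left at least 1.70. With normexp background correction and the 75th percentile, the interactions of cmpB (1.37, adjusted p = 0.0505 in limma) and cmpC (1.11, adjusted p = 0.0602) no longer passed. Both passed with normexp and quantile normalization. The decrease of the ATP synthase genes was smaller in the mutant for all 9 (median 0.98; camera, adjusted p = 9.72e-07, and 0.485 with an estimated correlation), with atpC (sll1327) at 1.31 ± 0.08. So was that of the nitrogen genes nrtB (sll1451, 1.64 ± 0.11), nrtA (sll1450, 1.47 ± 0.12) and glnA (slr1756, 1.29 ± 0.10). Of the phycobilisome genes 12 of 15 passed with positive interactions (median 0.86; camera, adjusted p = 1.02e-05, and 0.485 with an estimated correlation), including cpcG2 (sll1471, 1.50 ± 0.10). Adjusted over the list alone, these counts of 9 and 12 were the same.

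Negative interactions were found for slr0798 (-4.30 ± 0.15), slr0797 (-2.76 ± 0.10) and pgr5 (ssr2016, -2.26 ± 0.14), which were higher in the mutant at HC. The nblA genes, which rose in the WT, had interactions of -2.78 ± 0.08 (nblA1, ssl0452) and -1.90 ± 0.09 (nblA2, ssl0453). The pilin genes had interactions of -2.03 ± 0.10 (pilA2, sll1695) and -1.36 ± 0.12 (pilA1, sll1694). limma called 2154 of 8145 features for the interaction (1220 positive, 934 negative), of which 301 reached 2-fold (193 positive, 108 negative). Among coding genes 986 were called (541 positive, 445 negative). Positive interactions made up 56.6% of the features called, but 48.8% (1271 positive, 1336 negative) with quantile normalization. The count was 1069 without WT LC replicate 1, 1193 without mutant LC replicate 2, 1234 without mutant LC replicate 1, 1238 without WT LC replicate 2 and 1406 without both dim HC arrays, the last a fit chosen after seeing the data. normexp with the 75th percentile called 1402. With the authors' processed values 19 of 26 named interactions and the medians of 7 of 13 called lists were over 1.5 times smaller. The lowest ratio of a named interaction there to its main value was 0.08. With normexp 7 of 26 (75th percentile) and 8 of 26 (quantile normalization) named interactions were over 1.5 times smaller.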

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

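For the cmp genes, the comparison with the other carbon uptake genes and the values raised to the lowest signal were tests chosen only after the result was seen, and so were the count of slides and the comparison with other falling genes for the ATP synthase and phycobilisome genes.

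The response to LC differed between the strains for 2154 of 8145 features by the interaction test in limma. Among single genes, the difference was positive for cmpC (slr0043, 2.84), slr0042 (2.51), cmpD (slr0044, 1.76), cmpA (slr0040, 1.57), nrtB (sll1451, 1.64), nrtA (sll1450, 1.47), glnA (slr1756, 1.29), glnN (slr0288, 1.29), cpcG2 (sll1471, 1.50), cpcC2 (sll1579, 1.20), atpC (sll1327, 1.31), atpA (sll1326, 1.03), chlL (slr0749, 1.42), chlB (slr0772, 1.37) and gap1 (slr0884, 1.09). It was negative for slr0798 (-4.30), nblA1 (ssl0452, -2.78), slr0797 (-2.76), pgr5 (ssr2016, -2.26), pilA2 (sll1695, -2.03), sll0792 (-2.01), nblA2 (ssl0453, -1.90), hliB (ssr2595, -1.76), pilA1 (sll1694, -1.36) and sll0794 (-1.16). cmpB (slr0041) was fitted at 3.78, but it was not above background in the mutant at HC and its bound left at least 1.70. The calls of cmpB (1.37, adjusted p = 0.0505 in limma) and cmpC (1.11, adjusted p = 0.0602) ended with normexp background correction. All of these differences are log2 values, response of the mutant minus that of the WT. For the cmp genes, slr0042, chlL, chlB and gap1 they largely repeat strain differences of opposite sign at HC. Those were -2.88 for cmpC, -1.64 for chlL, -1.49 for chlB and -1.15 for gap1.

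Of the gene lists, 13 passed camera for the interaction with the preset correlation, and 0 did with an estimated one (smallest adjusted p = 0.485 with an estimated correlation). Their median interactions were 0.98 for ATP synthase, 0.93 for nitrogen assimilation, 0.86 for the phycobilisome, 0.52 for the hydrogenase, 0.46 for inducible carbon uptake, 0.38 for the Calvin cycle, 0.35 for photosystem I, 0.34 for electron carriers and oxidases, 0.34 for photosystem II, 0.33 for sugar catabolism, 0.31 for tetrapyrrole synthesis, 0.26 for the mnh operon and -0.27 for phosphate uptake. The Calvin cycle list did not pass camera without mutant HC replicate 1 (adjusted p = 0.0542) or WT LC replicate 2 (adjusted p = 0.0632), and the mnh list did not without mutant LC replicate 2 (adjusted p = 0.0553) or WT LC replicate 1 (adjusted p = 0.0522), nor with normexp and quantile normalization (median 0.20, adjusted p = 0.0744). Without WT HC replicate 2 the photosystem II median was 0.22, and without mutant HC replicate 1 the phosphate median was -0.48. With the authors' processed values 7 of the 13 medians were over 1.5 times smaller, among them those of nitrogen assimilation (0.55), the hydrogenase (0.21) and inducible carbon uptake (0.21). With quantile normalization alone 3 were, those of inducible carbon uptake (0.28), tetrapyrrole synthesis (0.17) and the mnh operon (0.17). The number was 2 with normexp and the 75th percentile and 3 with normexp and quantile normalization.

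The cmp genes and slr0042, which encode or adjoin the bicarbonate transporter, were lower in the mutant at HC. If 1 array were out of line, at least 1 pair of arrays would show little difference, but the smallest median difference over the 5 genes in the 4 pairs of single arrays was -2.45, or -1.66 with mutant values raised to the lowest signal above background, since most readings of cmpB, cmpC and slr0042 there were not above it. An offset of dim features would shift other features at the same level, but 1029 other coding features in the same range of WT levels had a median of -0.0723 ± 0.0107 (bootstrap SE). A lower state of carbon limitation in the mutant cultures, if it acted on all inducible carbon uptake genes, would lower the other 6 too. Their median was 0.0841 (from -0.22 to 0.56). A carbon state that acts on the cmp genes and slr0042 alone would not be seen by this test and stays open. A change of the cmp genes and slr0042 apart from the other inducible uptake genes, tied to the mutation or to the way this mutant strain was built or grown with kanamycin, may remain as a hypothesis, found and tested on the same data; the design cannot separate these, and a complemented strain grown with kanamycin would.

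All 9 ATP synthase genes and 12 of 15 phycobilisome genes, which fell in the WT at LC, were higher in the mutant than in the WT there (camera, adjusted p = 1.29e-07 and 6.58e-06, but adjusted p = 0.485 for both with an estimated correlation). A smaller response of all genes in the mutant would shrink the genes that rose as well. Over 251 coding genes with a mean response above 1 the strain difference per unit of response was 0.045 ± 0.033. Large responses weigh most in this value. The set held the cmp genes and slr0042, whose larger rise in the mutant rests in part on background readings. Without them the value was not computed, so it does not settle the point for the genes that rose. The 559 other coding genes with a mean response below -1 had -0.0720 ± 0.0135 per unit, a slightly smaller fall in the mutant. The value was -0.389 ± 0.014 for the ATP synthase and -0.651 ± 0.133 for the phycobilisome genes. All 15 phycobilisome genes entered whatever their response, so they are not matched to the 559. Part of their value may come from HC, where 6 of 15 were lower in the mutant and 0 higher (median -0.27). A trend with brightness would shift other genes of the same level. The 2370 other coding features in the range of WT levels of these genes had a median of -0.0587 ± 0.00816. That range held most of the 3329 coding features, so this median cannot show a trend within it. A difference between slides cannot be told apart from the strain here, since 0 slides held LC arrays of both strains, and a weaker acclimation of these gene groups in the mutant stays an untested hypothesis, for which LC arrays of the WT, the mutant and a complemented strain grown with kanamycin would be needed on 1 slide.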

How the results depend on the processing

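The fit without the dim HC arrays, the crossed pairing and cyclic loess were chosen after seeing the data. Of 187 called values of named genes, 0 changed direction and 184 kept their call under each alternative that gave them a value (161 of the 187 with only the groups compared, 172 with the filter on all 8 arrays and 151 without the dim HC arrays, and none with single probes); the other 3 (sml0013 in the WT response, and the interactions of cmpB and cmpC) lost it with normexp background correction and the 75th percentile. Of the 53 calls of gene lists, 0 changed direction and 49 kept their call with normexp and quantile normalization. With a correlation within each list estimated from the same 8 arrays, 0 passed. A higher correlation cannot account for every lost call. The carboxysome and Rubisco list had an estimate of -0.08, below the preset value. Its adjusted p in camera for the mutant against the WT at LC still went from 0.000449 to 0.485. Sugar catabolism, with an estimate of -0.0009, went from 0.0103 to 0.485 for the interaction. All other lists called had estimates above the preset value. The cause of the loss was not tested.

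For the mutant against the WT at HC, the count of 2380 fell to 1550 with normexp and the 75th percentile (the cause was not tested), to 1148 with only the 4 arrays compared, which are those of 1 slide and leave fewer arrays to estimate the spread, and to 991 without the dim HC arrays, which leaves each HC group with 1 array assumed to vary like the others. For the interaction, 2154 fell to 1402 with normexp and the 75th percentile (the cause was not tested) and to 1406 without the dim HC arrays. Tested as 18692 single probes, 14395 and 14584 probes changed in the WT and mutant responses, 4792 and 7663 between the strains at HC and LC and 4704 for the interaction, from more units tested. Apart from single probes, the lowest count under the alternatives in which no single array was left out was 5858 for the WT response, 5785 for the mutant response and 2368 for the mutant against the WT at LC, all with normexp and the 75th percentile. The correlation of the responses, 0.911, was 0.926 with normexp and the 75th percentile, 0.923 with normexp and quantile normalization, 0.931 with the authors' processed values and 0.904 without the dim HC arrays (the cause was not tested).

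sml0013 was lower in the mutant under every alternative that tested it. Among those that left out no single array, its fitted log2 changes ran from -7.13 to -2.55 at HC and from -7.10 to -2.80 at LC, but the mutant probe was not above background, so only the bounds of 29.7-fold and 27.0-fold measure the size. The smallest came from the authors' processed values, and 92 of the 187 named log2 changes were over 1.5 times smaller there. So were 26 with normexp and the 75th percentile, 28 with normexp and quantile normalization, and 2 with quantile normalization alone. The filter on all 8 arrays left sml0013 untested. Signal over background sets how far a low gene can be followed, as the bounds for sml0013, cmpB and flv4 show.

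With 1 array left out at a time, the counts ran from 5784 to 6446 (WT response), 5843 to 6450 (mutant response), 1407 to 1977 (mutant against WT at HC), 1853 to 3376 (at LC) and 1069 to 1720 (interaction). The fitted log2 change of sml0013, against background readings and so no measure of how stable its fold is, ran from -7.19 to -7.07 at HC and -7.14 to -6.93 at LC, the correlation from 0.906 to 0.912 and the number of list calls from 51 to 56. The count at HC fell by over 1.5 times without mutant HC replicate 1 (1407) or WT HC replicate 2 (1554). At LC it did so without WT LC replicate 1 (1853) or 2 (2105) or mutant LC replicate 1 (2038) or 2 (2067), and for the interaction likewise (1069, 1238, 1234 and 1193).

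The replicate numbers were not taken to pair the samples, since the labels name nothing shared by a number and 2 arrays per group are too few to show it: deviations of same-numbered arrays correlated at 0.46 between the HC groups and 0.22 between the LC groups, and from -0.40 to -0.28 between HC and LC groups. With the replicate number as a block the counts were 6232 (WT response), 6236 (mutant response), 1862 (strains at HC), 2872 (strains at LC) and 1565 (interaction), and it ended no call of a named gene or list. With the pairing between HC and LC crossed, 6733 features were called in the WT response, 6725 in the mutant response, 3008 between the strains at HC, 4081 at LC and 2860 for the interaction.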

Other observations

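The count of slides for the antisense features was a test chosen only after the result was seen.

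4 genes outside the lists, chosen after their values were seen and not tested as a group, are given singly. slr0798 (a zinc exporter), sll0792 (its zinc-responsive repressor), slr0797 (a cobalt exporter) and sll0794 (its cobalt-responsive regulator) were higher in the mutant at HC, by 3.23 ± 0.11, 1.32 ± 0.06, 1.61 ± 0.07 and 0.64 ± 0.06. From HC to LC they rose in the WT, by 0.51 ± 0.11, 0.86 ± 0.06, 0.67 ± 0.07 and 0.55 ± 0.06, and fell in the mutant, with log2 changes of -3.79 ± 0.11, -1.15 ± 0.06, -2.09 ± 0.07 and -0.61 ± 0.06. At LC slr0798 (-1.07 ± 0.11), slr0797 (-1.15 ± 0.07) and sll0792 (-0.70 ± 0.06) were lower in the mutant than in the WT. The fitted level of sll0794 was lower there too, since its interaction of -1.16 ± 0.09 outweighs its difference at HC. All of these printed values passed limma.

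Noncoding RNAs were among the largest changes at LC. NC-1136 rose by 7.33 ± 0.10 in the WT and at least 203-fold in the mutant, where it was not above background at HC. NC-425 rose by 7.05 ± 0.08 in the WT and 7.24 ± 0.08 in the mutant, and NC-1567 at least 62.4-fold in the WT. NC-240 stood at -4.44 ± 0.08 in the WT and -5.12 ± 0.08 in the mutant. Of 541 noncoding features, 263 were higher and 144 lower in the WT, and 275 higher and 135 lower in the mutant (limma).

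Antisense features were mostly higher at LC: 981 of 1494 were higher and 183 lower in the WT (median log2 change 0.60), and 1046 were higher and 159 lower in the mutant (median 0.73), and both medians stayed positive under all 7 scalings (0.24 to 0.64 and 0.23 to 0.73). A rise of dim features of every kind would move coding features of the same level alike, but the antisense median lay 0.684 ± 0.029 (bootstrap SE) above them in the WT and 0.746 in the mutant. The dim HC arrays could account for all of the difference only if it vanished against the brighter HC array of each strain. There it was 0.617 ± 0.024 in the WT and 0.829 in the mutant. A part of the difference could still come from the dim arrays. A difference between slides cannot be told apart, since 0 slides held both HC and LC arrays. Background differed as well: negative control spots stood at 42.1% to 50.0% of the median spot signal on LC arrays and 30.4% to 40.3% on HC arrays. Whether this adds to the antisense rise was not tested. Other kinds of features also lay above the coding medians of -0.12 (WT) and -0.11 (mutant). Structural RNA stood at 0.90 and 0.69, noncoding features at 0.33 and 0.33, and unclassed features at 0.59 and 0.75. Internal features stood at 0.12 and 0.15 and 5' UTR features at -0.06 and -0.07. A rise of antisense RNA relative to coding RNA at LC, not particular to antisense RNA, may be the biology. It is a hypothesis found and tested on the same data, for which HC and LC arrays on 1 slide would be needed.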
